A study of Bos taurus with 6 samples.

How the data were processed

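RNA of whole testis from Angus bull calves was measured on Affymetrix bovine GeneChips, oligonucleotide arrays hybridised with 1 biotin-labelled sample each. The labels give 3 ages (2, 4 and 8 weeks) with 2 replicates per age, so 6 arrays in all. They name total RNA for all samples and a Trizol extraction for a single one. They do not say that the replicates of an age came from separate calves, so the p-values measure only the spread between these samples, which may be in part technical.

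The deposited values are signal intensities per probe set on a linear scale. Per the submitters' processing notes, the arrays were read with GCOS version 1.4.0.036. The summarisation settings, detection calls and test are not given in the sources used here. The values themselves show that each array had been scaled to 1 trimmed mean (125.02 to 125.03, with 2% of the values left out at each end). Rescaling to equal trimmed means therefore used factors of 0.999975 to 1.00002. The array holds 24128 probe sets. The 112 control probe sets were left out of all tests, which left 24016.

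Gene names came from the platform annotation paired with the probe sets. It gave 1 gene symbol for 13292 probe sets, several for 86 and none for 10638. Of the probe sets with 1 symbol, 13263 had an Entrez identifier in the ARS-UCD2.0 gene table, and 0 symbols differed from it. Probe sets with several symbols or none were tested and counted but not named, apart from a few unnamed ones in the closing section that were singled out after their values were seen. Apart from that gene table, the sources used here name no genome build, so no coordinates are given.

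Log2(value + 16) was tested with limma 3.58.1 in R 4.3.3, with lmFit and eBayes(trend=TRUE) and 1 coefficient per age over all 6 arrays. This left 3 residual degrees of freedom, to which the variance prior added 7.52. A fold change on this scale understates the change of dim probe sets. The upper 60% of probe sets by mean log2 value were tested (14409 probe sets, at or above a signal of about 30.1 on the geometric scale), 9133 of them with 1 symbol. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The comparisons were 8 against 2 weeks, 4 against 2 weeks, 8 against 4 weeks, a moderated F test over the 3 ages, and the difference between the second step (4 to 8 weeks) and the first (2 to 4 weeks).

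Before the data were examined, 24 gene lists were fixed. They cover the cell types of the prepubertal testis, steroid, cholesterol, retinoid and growth factor pathways, proliferation, respiration, translation and stress, and tissues that a dissection can bring along (blood, leukocytes, skeletal muscle, fat, epididymis). Lists were tested two-sided with limma's camera at a preset inter-gene correlation of 0.01, on the brightest probe set of each of 7008 genes, for the 21 lists with at least 5 measured genes. A gene counts as measured here if a named probe set of it lies above the filter. Camera was repeated with the correlation estimated per list, and fry was run on the same lists. With an estimated correlation limma rests camera's p-value on the 3 residual degrees of freedom. Passing the adjusted threshold there is therefore hard whatever the correlation. In some lists called at the preset, the estimate was also far above it. It was 0.565 for leukocyte, 0.588 for cholesterol, 0.644 for oxidative phosphorylation and 0.414 for skeletal muscle genes. Camera p-values of these lists at the preset may therefore be too small. Beside each list's count over all probe sets stands the count adjusted over the list alone.

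The rule for named genes was also fixed beforehand. Where fewer than 10 named probe sets passed the threshold, as happened in each comparison, it takes the 8 higher and 8 lower genes with the smallest p, reported as not past the threshold, each gene being judged by its brightest probe set alone. It adds up to 4 members per list with the smallest p at 8 against 2 weeks, and a panel of 23 testis genes whatever their values. Of the panel, 20 genes have a named probe set on this array, and 17 lie above the filter. For HSD17B3, DDX4 and MKI67 no probe set is named here.

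The fit was tested on simulated data for 8 against 2 weeks over 14409 genes, with 50 genes changed at each fold size. It recovered 42% of the 2-fold changes, 92% of the 3-fold changes and 100% of the 4-fold and 6-fold changes, with 11 false calls. Of 21 simulated lists, the list shifted by 0.5 on the log2 scale was called, and 0 of the others. The simulated genes were independent, whereas the estimated correlation was 0.565 in the leukocyte, 0.588 in the cholesterol and 0.644 in the oxidative phosphorylation list. False calls of lists with correlated genes were therefore not assessed. The simulated noise of a gene also had the same spread on all arrays, so no simulated array stood apart. It was drawn from variances already moderated by the fit, and planting many changes together eases the adjusted threshold. The shares recovered may therefore be too high for the real data. There, an unnamed probe set with a 5.61-fold difference between 8 and 2 weeks had a limma adjusted p of 0.0713 and was not called. An absence of calls thus does not exclude large changes.

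The number of arrays limits the precision. The median standard error of a log2 change between any pair of ages was 0.26. As a measure of background, the 27 probe sets for Bacillus spike-in transcripts had a 95th percentile of 13.8 and a highest signal of 28.1 over the 6 arrays. With 2 samples per age, an exact two-sided permutation test of a pair of ages cannot go below p = 0.333, and the 15 ways to group 6 samples into 3 pairs cannot go below p = 0.0667.

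The alternatives were other pseudocounts (1 and 64), no filter and a stricter filter, quantile normalization, values without rescaling, other variance models, the replicate number as a block, fits of only the samples compared, slopes on age, camera with estimated correlations, the mean of a gene's probe sets, other probe sets of named genes, and each sample left out in turn. Leaving out a pair of samples together was added after seeing the data. Their effects stand in the closing section.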

Results

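Testis transcript levels were compared between bull calves of 2, 4 and 8 weeks of age, the weeks after birth in which the bovine testis holds seminiferous cords with Sertoli cells and immature germ cells, surrounded by Leydig cells, vessels and peritubular cells. Each age is represented by 2 arrays. The median probe set signal per array lay between 46.3 and 52.4, and 25.3% to 30.1% of the values were under 16. Signals are scaled intensities, given as mean ± SD with n = 2 per age unless each replicate is listed. The correlation of log2 values of an array with the others averaged 0.953 to 0.960 for 5 arrays and 0.917 for 2wk replicate 2. Between replicates of 1 age it was 0.918 at 2 weeks, 0.961 at 4 weeks and 0.974 at 8 weeks. The highest of all pairs was 0.975, between 2wk replicate 1 and 4wk replicate 1. Arrays of 1 age were thus not always the most alike. The SD over probe sets of the log2 difference between replicates was 0.58 at 2 weeks, 0.39 at 4 weeks and 0.32 at 8 weeks.

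Most of the Sertoli and Leydig cell genes of the panel had means that differed little between ages. Signals of different probe sets are not ranked against each other, since probes differ in response. Among Sertoli cell products, the signal of AMH, the hormone that makes the Müllerian ducts regress, was 2466 ± 409 at 2 weeks, 2181 ± 303 at 4 weeks and 2202 ± 369 at 8 weeks. INHA, the inhibin alpha subunit, stood at 5446 ± 1020, 5660 ± 797 and 5561 ± 595. FSHR, the receptor for follicle-stimulating hormone, was at 155 ± 21.8, 170 ± 22.5 and 139 ± 32.5, and INHBA at 727 ± 114, 884 ± 42.9 and 785 ± 15.6. Among Leydig cell genes, INSL3, a hormone of testis descent, was at 6424 ± 1800, 6805 ± 1080 and 6864 ± 291. STAR, which brings cholesterol into mitochondria, was at 2911 ± 763, 2589 ± 1290 and 3296 ± 372. The steroidogenic enzymes CYP17A1 (2644 ± 1060 and 3049 ± 869 at 2 and 8 weeks), CYP11A1 (445 ± 79.8 and 482 ± 19.2) and HSD3B1 (440 ± 211 and 292 ± 37.3) also overlapped between these ages. The luteinizing hormone receptor LHCGR had no overlap between 2 and 8 weeks, at 35.0 ± 3.32, 54.4 ± 28.8 and 55.1 ± 1.77.

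Among germ cell genes, KIT was at 251 ± 32.8, 273 ± 26.0 and 306 ± 21 at the 3 ages. UCHL1, found in gonocytes and spermatogonia, was at 791 ± 70.9, 576 ± 117 and 702 ± 271, and the pluripotency factor POU5F1 at 57.5 ± 29.8, 46.5 ± 10.5 and 39.9 ± 15.8. The spermatid genes PRM1 (8.30 ± 3.25 to 15.5 ± 0.141) and TNP1 (9.30 ± 4.67 to 15.5 ± 4.24) and the aromatase gene CYP19A1 (4.60 ± 1.41 at 2 weeks, 17.1 ± 11.9 at 8 weeks) lay below the filter and within the range of the Bacillus control probe sets, so no direction is read from them. Haemoglobin transcripts differed between replicates of 1 age. HBB was at 12.5 in 2wk replicate 1 and 317.9 in 2wk replicate 2, against 43.6 to 109.4 at the later ages, and HBG at 19.7 and 62.6, against 15.6 to 46.0. With limma, the adjusted p for 8 against 2 weeks was at least 0.553 for each panel gene above the filter.

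**Figure D1:**
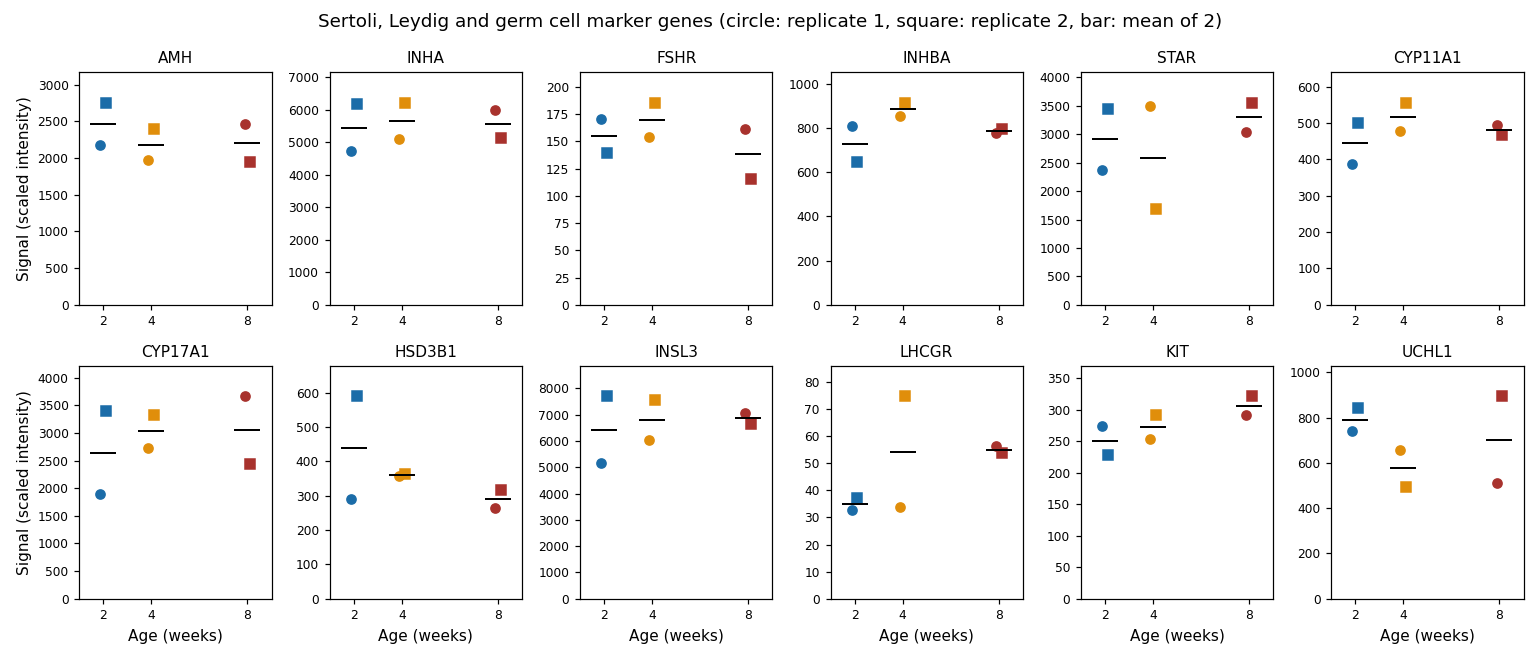
Signal (scaled intensity, linear axis from 0) of 12 Sertoli, Leydig and germ cell genes against age in weeks (circles replicate 1, squares replicate 2, bars the mean of 2 samples). The INSL3 values run from 5153 to 7695.

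The widest comparison, 8 against 2 weeks, asks which transcripts differ over the whole period. NT5E, an ectoenzyme that makes extracellular adenosine, had a signal of 47.3 ± 3.25 at 2 weeks, 95.1 ± 3.68 at 4 weeks and 173 ± 19 at 8 weeks, a log2 difference of 1.57 ± 0.23 (SE) between 8 and 2 weeks. GJA1, a gap junction protein that joins Sertoli cells, was at 838 ± 138, 1417 ± 17.2 and 1995 ± 224. SERPINI1, the protease inhibitor neuroserpin, was at 172 ± 106, 442 ± 52.0 and 656 ± 14.8. In the other direction, PTI, a Kunitz-type trypsin inhibitor, was at 125 ± 20.8, 89.8 ± 39.5 and 16.7 ± 3.75, and DLK1, an imprinted Notch-pathway ligand of fetal tissues, at 432 ± 195, 156 ± 3.39 and 126 ± 21.3. None of these passed the threshold.

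Of the 14409 probe sets tested, 0 differed between 8 and 2 weeks at an adjusted p under 0.05 in limma, and the smallest adjusted p was 0.0713. At an unadjusted p under 0.05 there were 1002 (510 higher and 492 lower at 8 weeks), where 720 are expected by chance. The 16 genes named by the rule therefore stand below the threshold, with limma adjusted p-values from 0.139 to 0.233. In each the samples of both ages did not overlap, which the choice by smallest p makes likely and which adds no support. The higher ones also include C5H12orf75 (log2 difference 1.46, and 0.55 with its other probe set), PLEKHG1 (1.42) and CCDC69 (1.25). Also among them are NUDT4, an inositol pyrophosphate phosphatase (1.20, and 0.69 with its other probe set), and CYP51A1, the lanosterol demethylase of cholesterol synthesis (1.43). The lower ones include the immediate early transcription factor EGR1 (-1.53), LOC100300510, the microfibril protein MFAP2 (-1.58), the cell cycle arrest gene RPRM (-1.62), the sulfonylurea receptor ABCC8 (-1.66) and the dipeptidase DPEP1 (-1.43). At 8 weeks the signals of PTI (14 and 19.3) and LOC100300510 (13.7 and 3.2) lay below the highest Bacillus control (28.1), so no size of change is read from them.

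**Figure D2:**
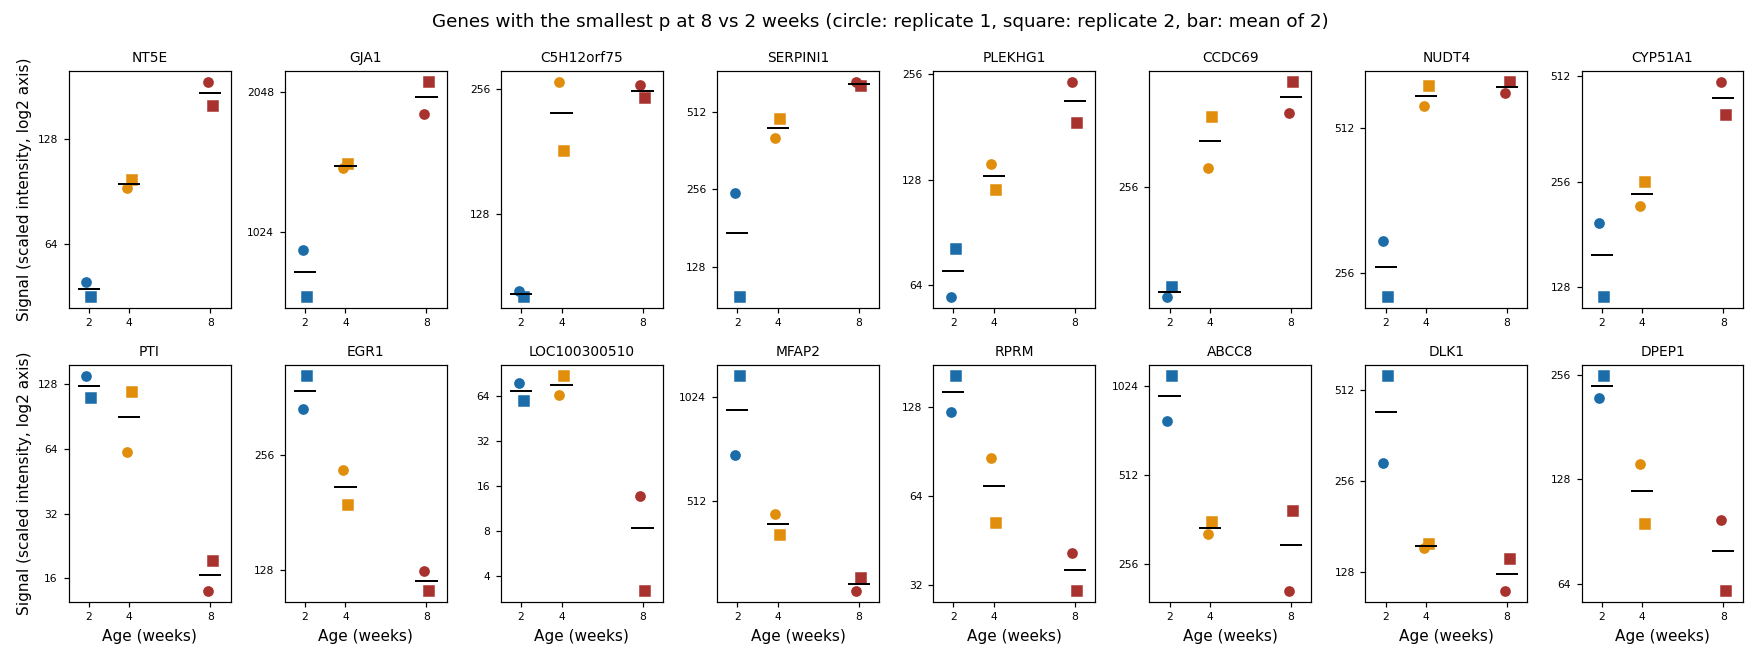
Signal (scaled intensity, log2 axis) of the 8 higher and 8 lower genes with the smallest p between 8 and 2 weeks, against age in weeks (circles replicate 1, squares replicate 2, bars the mean of 2 samples). NT5E runs from 45.0 to 49.6 at 2 weeks and from 159.1 to 186.0 at 8 weeks, and PTI from 110.6 to 140.0 and from 14 to 19.3.

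Genes of cholesterol biosynthesis rose as a group from 2 to 8 weeks, with 14 of the 17 measured members higher and a mean log2 change of 0.47 (limma camera adjusted p = 2.46e-05, adjusted p = 0.661 with an estimated correlation; fry adjusted p = 0.6). CYP51A1 was at 158 ± 53.5 and 445 ± 68.6, HMGCS1 (the enzyme that makes hydroxymethylglutaryl-CoA) at 807 ± 36.3 and 2077 ± 788, the sterol oxidase MSMO1 at 806 ± 19.2 and 1674 ± 56.4, and LSS (lanosterol synthase) at 66.3 ± 13.7 and 134 ± 40.7. No member passed the threshold over all probe sets, and 3 did when adjusted over the list alone. Per array, the mean of the list relative to all 6 arrays was -0.47 and -0.01 at 2 weeks, -0.29 and 0.29 at 4 weeks and 0.37 and 0.10 at 8 weeks. Without 2wk replicate 1 the mean change was 0.25, with a camera adjusted p of 0.333.

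Endothelial genes fell from 2 to 8 weeks, with 13 of 16 members lower and a mean log2 change of -0.34 (limma camera adjusted p = 0.00556, adjusted p = 0.661 with an estimated correlation; fry adjusted p = 0.0216). The tight junction gene CLDN5 was at 471 ± 144 and 229 ± 73.5, the transcription factor SOX18 at 123 ± 11.5 and 70.8 ± 8.63, vascular cadherin CDH5 at 153 ± 12.9 and 92.6 ± 19.9, and PECAM1 at 114 ± 6.65 and 69.5 ± 6.15. Of its members, 0 passed over all probe sets and 0 when adjusted over the list alone. The mean of the list per array was 0.17 and 0.16 at 2 weeks, -0.02 and 0.03 at 4 weeks and -0.18 and -0.17 at 8 weeks. The call was lost without 2wk replicate 1 (mean -0.33, camera adjusted p = 0.314) and without the filter on low values (mean -0.27, camera adjusted p = 0.0811).

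Leukocyte genes also fell in this comparison, with 32 of 33 members lower and a mean log2 change of -0.44 (limma camera adjusted p = 2.46e-05, adjusted p = 0.661 with an estimated correlation; fry adjusted p = 0.6). The monocyte receptor CD14 was at 85.2 ± 34.0 and 25.9 ± 5.87, the T cell receptor chains CD3E and CD3D at 206 ± 41.4 and 129 ± 20.4 and at 179 ± 105 and 89.8 ± 5.02, and the chemokine receptor CXCR4 at 89.2 ± 13.2 and 49.5 ± 26.7. CD14 was at 21.7 in 8wk replicate 2, below the highest Bacillus control (28.1), so no size of its change is read. Of the list's members, 0 passed over all probe sets and 0 when adjusted over the list alone. The list stood at 0.72 in 2wk replicate 2 and between -0.23 and -0.02 in the other 5 arrays, and without that array the mean change was 0.03 with a camera adjusted p of 0.923.

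The other 18 tested lists did not pass the threshold between 8 and 2 weeks. The closest were the retinoid pathway (7 of 10 members lower, mean -0.41, limma camera adjusted p = 0.0662) and skeletal muscle genes (7 of 8 lower, mean -0.38, adjusted p = 0.0907). Within the retinoid list, CRABP2 and CRABP1, cytoplasmic retinoic acid binding proteins, were at 100 ± 25.2 and 34.9 ± 1.84 and at 106 ± 17.5 and 37.9 ± 0.495, the retinoid transporter gene STRA6 at 331 ± 97.2 and 167 ± 89.4, and ALDH1A1, which makes retinoic acid, was higher at 8 weeks (3019 ± 95.8 and 5306 ± 103). Adjusted over the list alone, 3 retinoid genes passed, against 0 over all probe sets. Among muscle genes, TNNC1 was at 146 ± 118 and 36.5 ± 1.13, and CKM at 1050 ± 104 and 770 ± 45.5.

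The lists for Sertoli, Leydig, germ and peritubular cells of the testis did not pass the threshold. Sertoli genes had a mean log2 change of 0.18 (10 higher, 7 lower), in which the tight junction gene CLDN11 went from 34.7 ± 7.07 to 238 ± 54.0 and GJA1 as given above. Over all probe sets 0 Sertoli genes passed, and 2 passed when adjusted over the list alone. Leydig and steroidogenic genes had a mean of 0.04 (8 higher, 4 lower), gonocyte and spermatogonial genes -0.12 (3 higher, 7 lower), with EPCAM at 64.2 ± 12.3 and 43.1 ± 6.15 and MAEL at 115 ± 15.8 and 83.9 ± 22, and meiosis genes 0.22 (4 higher, 1 lower), with the testis chaperone HSPA2 at 99.3 ± 16.1 and 173 ± 8.77. Smooth muscle and peritubular genes had a mean of 0.05, with CSRP1 at 157 ± 36.7 and 98.1 ± 4.67 and RGS5 at 218 ± 155 and 386 ± 83.6. Adipocyte genes had a mean of -0.11, with SCD at 540 ± 68.6 and 792 ± 87.2. The spermatid, erythroid and epididymis lists had 3, 2 and 1 genes above the filter and were not tested.

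Growth factor and matrix lists held single genes with large differences. The insulin-like growth factor list had a mean of -0.22 (6 of 11 lower), with the binding protein IGFBP3 at 1223 ± 549 and 402 ± 8.27 and the growth factor IGF2 at 3168 ± 1010 and 1595 ± 267. Of its genes, 0 passed over all probe sets and 2 when adjusted over the list alone. Imprinted and fetal growth genes had a mean of -0.19 (10 of 17 lower, with DLK1 and IGF2 first), and 2 passed when adjusted over the list alone. Extracellular matrix genes had a mean of -0.07 (27 of 40 lower), with MFAP2 at 937 ± 345 and 292 ± 17.7 and the basement membrane collagen COL18A1 at 153 ± 0.283 and 307 ± 14.8, and 2 passed when adjusted over the list alone. TGF-beta family genes had a mean of -0.16 (12 of 19 lower), with TGFB3 at 83.5 ± 5.16 and 53.9 ± 3.39 and BMP7 at 44.3 ± 20.4 and 21 ± 7.28. Angiogenic factors and receptors had a mean of -0.01, with VEGFA at 121 ± 24.3 and 162 ± 5.44 and ANGPT1 at 44.8 ± 4.38 and 24.6 ± 3.96. At 8 weeks BMP7 (15.8 and 26.1) and ANGPT1 (27.4 and 21.8) lay below the highest Bacillus control (28.1), so no size of change is read from them.

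In the lists on cell state, cell cycle genes had a mean of 0.02 (26 higher, 27 lower), with the spindle gene TPX2 at 130 ± 8.84 and 224 ± 42.2 and HMMR at 111 ± 26.5 and 228 ± 107. Immediate early and heat shock genes had a mean of -0.10. EGR1 was at 377 ± 52.8 and 120 ± 9.97, IER2 at 350 ± 49.5 and 190 ± 45.5, and JUNB at 185 ± 52.5 and 99.8 ± 28.3. The orphan receptor NR4A1 was higher at the later age (30.2 ± 3.75 and 78.7 ± 6.58). It was at 27.5 in 2wk replicate 2, below the highest Bacillus control (28.1), so no size of its change is read. Of the list's genes 0 passed over all probe sets and 3 when adjusted over the list alone. Oxidative phosphorylation genes had a mean of -0.14 (51 of 65 lower), with ATP5MC1 at 563 ± 135 and 381 ± 28.0. Glutathione and detoxification genes had a mean of -0.01, with MGST1 at 239 ± 31.3 and 423 ± 124 and GCLM at 54.1 ± 22.9 and 90.9 ± 3.89. Ribosomal protein genes had a mean of -0.04, with RPS9 at 4301 ± 1270 and 3341 ± 103 and RPL29 at 6189 ± 1750 and 5226 ± 369. For the testis cell type, adipocyte, growth factor, matrix and cell state lists the limma camera adjusted p was at least 0.186.

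**Figure D3:**
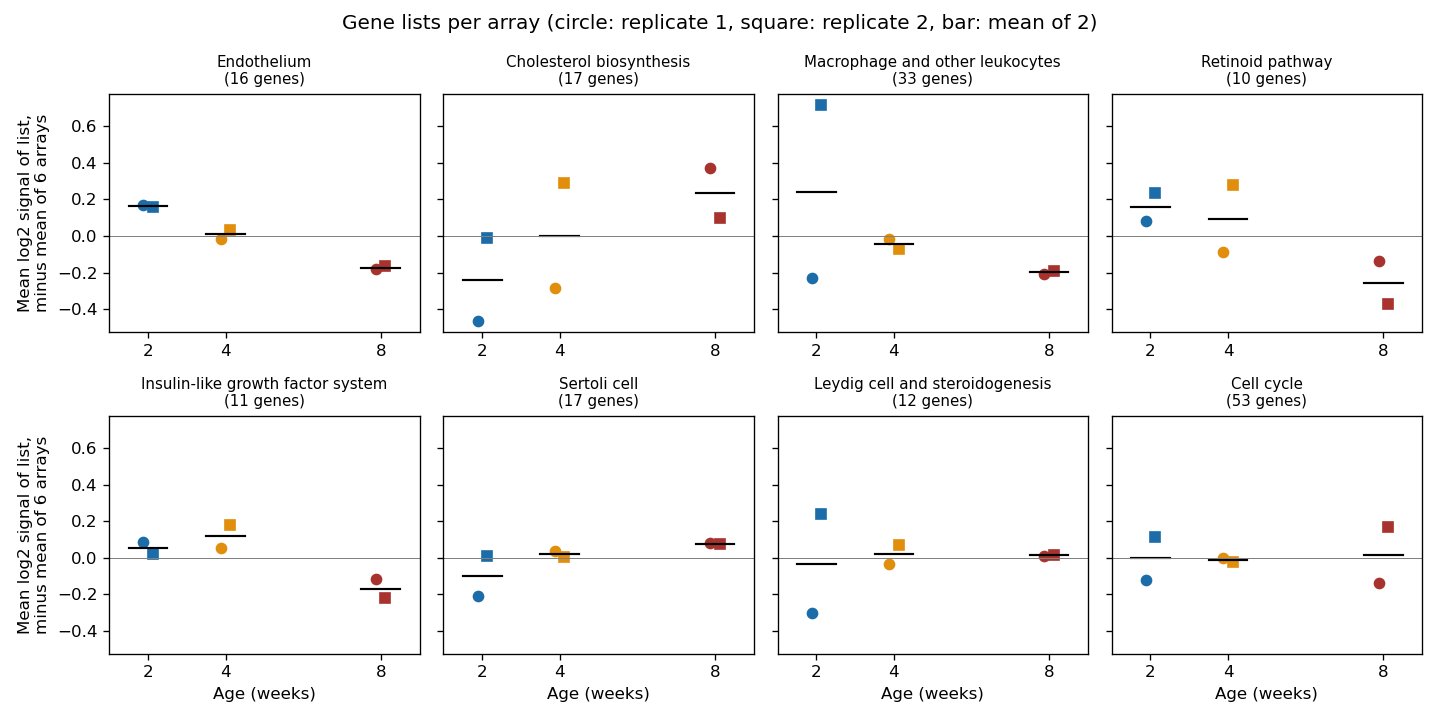
Mean log2 signal of 8 gene lists per array, minus the mean over the 6 arrays, against age in weeks (circles replicate 1, squares replicate 2, bars the mean of 2 samples). The endothelial list runs from 0.16 to 0.17 at 2 weeks and from -0.18 to -0.17 at 8 weeks, and the leukocyte list stands at 0.72 in 2wk replicate 2 alone.

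The comparison of 4 with 2 weeks covers the first step. NDRG4, a gene of the N-myc downstream regulated family, was at 31.6 ± 2.19 at 2 weeks and 109 ± 12.4 at 4 weeks (log2 difference 1.39 ± 0.24, SE), and TBC1D4, a Rab regulator of glucose transport, at 130 ± 42.3 and 461 ± 112. CRABP1 was at 106 ± 17.5 and 27.3 ± 14, and LOC508666 at 720 ± 418 and 32.9 ± 10.2, although 8wk replicate 1 returned to 544.2 and 8wk replicate 2 was at 47.3. The remaining higher genes were C5H12orf75 (log2 difference 1.27), NUDT4 (1.14), ZBTB44 (1.38), CCDC69 (0.95), SERPINI1 (1.40) and PCSK1N, an inhibitor of prohormone convertases (0.88). With their other probe sets C5H12orf75 gave 0.70 and NUDT4 0.73. The remaining lower genes were ABCC8 (-1.42), DLK1 (-1.31), the lipase inhibitor G0S2 (116 ± 11.4 and 49.9 ± 0.778), CD14 (85.2 ± 34.0 and 27.5 ± 2.12), MFAP2 (-1.03) and the iron-sulfur cluster gene GLRX5 (-1.28). For CRABP1, CD14 and LOC508666 at least 1 of the 4-week samples lay below the highest Bacillus control, so no size of change is read from them. In limma 0 probe sets passed, and the adjusted p of each of these genes was 0.944. At an unadjusted p under 0.05 there were 519 (288 higher, 231 lower), below the 720 expected by chance.

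Between 4 and 2 weeks 5 lists passed in limma camera. Leukocyte genes fell (31 of 33 lower, mean -0.29, adjusted p = 0.00418, adjusted p = 0.873 with an estimated correlation), and oxidative phosphorylation genes fell (56 of 65 lower, mean -0.16, adjusted p = 0.0102, adjusted p = 0.938 with an estimated correlation). Both lists were highest in 2wk replicate 2 (0.72 and 0.33), and without that array their mean changes turned to 0.19 (adjusted p = 0.0344) and 0.06 (adjusted p = 0.167). Without 4wk replicate 2 both calls were lost (-0.26, adjusted p = 0.085, and -0.19, adjusted p = 0.0605), and the oxidative phosphorylation call also without 4wk replicate 1 (-0.14, adjusted p = 0.0991) and with quantile normalization (-0.12, adjusted p = 0.0981). Cholesterol genes rose (12 of 17 higher, mean 0.24, adjusted p = 0.0102, adjusted p = 0.873 with an estimated correlation), with HMGCS1 at 1411 ± 448 and MSMO1 at 1346 ± 514 at 4 weeks. Without 4wk replicate 2 this change was -0.05 (adjusted p = 0.995), and without 2wk replicate 1 it was 0.01 (adjusted p = 0.809). Skeletal muscle genes fell (8 of 8 lower, mean -0.35, adjusted p = 0.0171, adjusted p = 0.873 with an estimated correlation), with CKM at 1050 ± 104 and 767 ± 33.1 and ENO3 at 101 ± 4.31 and 76.2 ± 2.97, and the mean was -0.14 without 2wk replicate 2 (adjusted p = 0.187) and -0.08 without the filter (adjusted p = 0.824). The call was also lost without 4wk replicate 1 (-0.31, adjusted p = 0.0991) or 4wk replicate 2 (-0.38, adjusted p = 0.0791), with pseudocount 1 (-0.33, adjusted p = 0.0718) and with the stricter filter (-0.23, adjusted p = 0.155), and the mean was -0.56 without 2wk replicate 1. Meiosis genes rose (5 of 5 higher, mean 0.25, adjusted p = 0.0445, adjusted p = 0.873 with an estimated correlation), with HSPA2 at 134 ± 13.8 and TEX12 at 113 ± 8.63 at 4 weeks, and among the single left-out arrays this call was kept only without 2wk replicate 2 (0.32, adjusted p = 0.0311). Without each of the others the mean was 0.19 to 0.28 (adjusted p from 0.0702 to 0.453), and the call was also lost with quantile normalization (0.22, adjusted p = 0.0806) and without the filter (0.12, adjusted p = 0.492). In these 5 lists 0 members passed over all probe sets and 0 when adjusted over the list alone. Only 5 of the 30 genes of the meiosis list and 8 of the 26 of the skeletal muscle list had a named probe set above the filter. The rest of these lists lay below the filter or had no named probe set, and nothing is said of them. With fry the adjusted p was 0.877 for the leukocyte, oxidative phosphorylation and cholesterol lists and 0.422 for the muscle and meiosis lists.

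The comparison of 8 with 4 weeks covers the second step. CA3, the carbonic anhydrase of muscle and fat, was at 43.6 ± 21.3 at 4 weeks and 131 ± 8.98 at 8 weeks (log2 difference 1.35 ± 0.29, SE), and NR4A1 at 36.0 ± 3.96 and 78.7 ± 6.58. LOC100300510 was at 75.6 ± 15.9 and 8.45 ± 7.42, CCS, the copper chaperone for superoxide dismutase, at 472 ± 147 and 171 ± 20.6, and IGFBP3 at 999 ± 287 and 402 ± 8.27 (-1.25 ± 0.31). The remaining higher genes were PRXL2A (log2 difference 0.79), NT5E (0.76, and 0.04 with its other probe set), CYP51A1 (0.86), the haem synthesis gene UROS (0.78), the aldo-keto reductase AKR1C4 and the calcium binding protein S100B (1132 ± 656 and 2101 ± 296). AKR1C4 was at 530.9 in 4wk replicate 1 and 22.4 in 4wk replicate 2, and another probe set for it gave a log2 difference of -0.81. The remaining lower genes were CRABP2 (-1.07), PTI, the peroxisome gene PEX6 (means of 81.2 and 21.9), the vascular addressin MADCAM1 (125 and 39) and TSPAN11 (74.8 and 27.3). LOC100300510, PTI, PEX6, MADCAM1 and TSPAN11 had at least 1 sample at 8 weeks below the highest Bacillus control, as AKR1C4 had at 4 weeks, so no size of change is read from them either. In limma 0 probe sets passed, with an adjusted p of 0.494 for LOC100300510 and 1 for each of the others. At an unadjusted p under 0.05 there were 360 (87 higher, 273 lower), below the 720 expected by chance.

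Between 8 and 4 weeks 4 lists passed in limma camera. Cholesterol genes rose (12 of 17 higher, mean 0.23, adjusted p = 0.016, adjusted p = 0.987 with an estimated correlation). Endothelial genes fell (14 of 16 lower, mean -0.18, adjusted p = 0.0183, adjusted p = 0.583 with an estimated correlation). Retinoid pathway genes fell (8 of 10 lower, mean -0.35, adjusted p = 0.0183, adjusted p = 0.653 with an estimated correlation), with CRABP2 at 91.2 ± 13.0 and 34.9 ± 1.84, while ALDH1A1 stood at 3962 ± 1120 and 5306 ± 103. The insulin-like growth factor system fell (10 of 11 lower, mean -0.29, adjusted p = 0.0192, adjusted p = 0.583 with an estimated correlation), with IGF2 at 2320 ± 35.1 and 1595 ± 267, IGFBP6 at 1341 ± 515 and 1284 ± 74.7, and IGFBP2 at 64 ± 9.62 and 36.2 ± 5.87. Over all probe sets 0 members passed, and adjusted over the list alone 1 retinoid gene, 1 insulin-like growth factor gene, 0 cholesterol genes and 0 endothelial genes did. With fry the adjusted p was 0.969 for the cholesterol, 0.599 for the retinoid, 0.0777 for the endothelial and 0.494 for the insulin-like growth factor list. The cholesterol change was -0.06 without 4wk replicate 1 (adjusted p = 0.897) and 0.10 without 8wk replicate 1 (adjusted p = 0.361), the retinoid change -0.17 without 4wk replicate 2 (adjusted p = 0.27) and -0.23 without 8wk replicate 2 (adjusted p = 0.183), against -0.53 without 4wk replicate 1 (adjusted p = 0.0078) and -0.47 without 8wk replicate 1 (adjusted p = 0.000413). The endothelial call was lost without any single 4- or 8-week array (mean -0.21 to -0.16, adjusted p from 0.0863 to 0.147), without the filter (-0.18, adjusted p = 0.0774), with the stricter filter (-0.13, adjusted p = 0.0787) and with quantile normalization (-0.13, adjusted p = 0.0505). The insulin-like growth factor call was lost without 4wk replicate 1 (-0.35, adjusted p = 0.095), 4wk replicate 2 (-0.22, adjusted p = 0.147) or 8wk replicate 2 (-0.24, adjusted p = 0.147) and without the filter (-0.21, adjusted p = 0.197).

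Across the 3 ages, the moderated F test of limma gave 0 probe sets at an adjusted p under 0.05, 558 at an unadjusted p under 0.05, and a smallest adjusted p of 0.175. For the difference between the second and the first step, limma gave 0 probe sets, 268 at an unadjusted p under 0.05 (100 with the second step more positive, 168 with it more negative) and a smallest adjusted p of 1. Of the lists, oxidative phosphorylation genes passed for this difference (53 of 65 with the second step more positive, mean 0.19, limma camera adjusted p = 0.0417, adjusted p = 0.922 with an estimated correlation; fry adjusted p = 0.974). Without 2wk replicate 2 the mean of this difference was -0.04.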

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

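All tests in this part were chosen after the results they measure had been seen, apart from the test of the difference between the steps and the fits with an array left out, with quantile normalization, without the filter and with an estimated correlation, which were fixed beforehand.

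Oxidative phosphorylation genes differed between the steps, by 0.193 on the log2 scale for the second minus the first, past the threshold of limma camera (adjusted p = 0.0417, adjusted p = 0.922 with an estimated correlation). The list mean was 0.329 in 2wk replicate 2 and between -0.128 and 0.00220 in the other arrays, and without that array the difference was -0.0352.

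Below the filter, 3 probe sets exceeded 10 times the highest Bacillus control signal on 1 array. An unnamed probe set was at 1255.7 in 2wk replicate 1 and between 0.700 and 5.90 elsewhere. Another unnamed one was at 466.2 in 4wk replicate 2 and between 0.5 and 4.20 elsewhere. The remaining one, for BOLA-DQB1, a chain of a class II major histocompatibility molecule, was at 644.1 in 2wk replicate 2 and between 3.90 and 13.8 elsewhere.

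Some BOLA-DQ probe sets were on or off between arrays of 1 age, while another, for BOLA-DQB1, was at 151 to 2377.7 on all 6. Of 10 BOLA-DQ probe sets that reached a signal of 64, 4 were highest in 2wk replicate 2, and 6 had their highest signals in 4wk replicate 2 and 8wk replicate 2. BOLA-DQA5 was at 656.9 in 2wk replicate 2 and at most 22.1 elsewhere, and the brightest BOLA-DQA2 probe set at 478.1 and 455.1 in 4wk and 8wk replicate 2 and at most 37.1 elsewhere. The amount of leukocytes does not account for the whole pattern, since 6 of these probe sets were highest, by more than 1 log2 unit, on arrays other than 2wk replicate 2, where the leukocyte list without BOLA genes was highest (0.718). Different BOLA-DQ haplotypes of the calves are a candidate explanation that stays open. BOLA-DQA and gene-specific BOLA-DQB probe sets were high together on 3 arrays, replicate 2 of each age, and on no other. The labels do not say what arrays of the same replicate number share. The 20 placements of 3 among 6 arrays are too few for a share under 0.05, and no genotype was analysed here.

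The array of 2wk replicate 2 stood apart from the rest, with a mean correlation of 0.917 and with 49.6% of the variance on a first principal component that separates it. The second component, with 17.3% of the variance, set 4wk replicate 2 apart (32.0, against -9.15 to -4.25 on the other arrays). Genes of splicing and nuclear speckles are a list drawn up once the data had been examined. In 2wk replicate 2 they were 0.918 lower than on the other 5 arrays, and 25 of 31 were lower than on each of them. RNA degradation with 3 prime bias is argued against, since the mean log2 ratio of 3 prime to 5 prime signal over 4 control transcripts was lower than on the other arrays by 0.229 (difference -0.229, SD of the others 0.0494). The shift was uneven. The unlogged ratios of eIF-4E (4.54) and ef1a (0.198) were below those of all other arrays. Those of gapd (0.967) and Cyph (1.39) lay within the range of the others. More leukocytes and blood in this sample may account for the leukocyte genes. These were higher by 0.86, above the highest of 10000 random lists matched on mean level (0.450). The random lists held unrelated genes, whereas the leukocyte list had an estimated correlation of 0.565. It had also been seen to be high on this array, so the comparison restates the pattern and adds no support. Dilution by leukocytes and blood is argued against for the splicing genes, since Sertoli genes were not lower there (0.0135 against the other 5 arrays). The Sertoli list lay 0.932 above the splicing list (SE over genes 0.186). Choosing the splicing list after its values were seen may have widened this gap. Intensity-dependent scaling is argued against too, since after quantile normalization the splicing list there was still -0.846 from the lowest other array, and a biological difference of this sample stays open and untested.

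The fall of endothelial genes with age is the list change with the least spread between replicates among those called. The call was nonetheless lost in limma camera with an estimated correlation (adjusted p = 0.661) and without the filter (change -0.266, adjusted p = 0.0811). It was also lost without 2wk replicate 1, where the change was -0.330. The estimated correlation of this list (-0.0205) lay below the preset 0.01, so correlation between its genes does not account for the first loss. The change itself does not rest on 2wk replicate 2, since from 2 to 8 weeks it was -0.344 without it, nor on the scaling between arrays, since it was -0.317 with quantile normalization. A dilution of all interstitial cells alike cannot be decided from the lists. The mean change of smooth muscle genes (0.0548, with 8 higher and 7 lower) lay 0.392 above that of endothelial genes (-0.337, SE of the difference 0.147). A permutation test over genes gave a two-sided p of 0.0116. The endothelial list was picked for its fall and genes are not independent replicates, so no conclusion is drawn from this p. Leydig cell genes, also interstitial, had a mean change of 0.0443 (8 higher and 4 lower). Their list stood at -0.304 and 0.24 in the 2-week arrays, too far apart to decide the question. Age and a difference between single calves cannot be told apart. Of the 15 groupings of the 6 arrays into 3 pairs, 1, the real one, gave pairs as tight. With 15 groupings a share under 0.05 cannot be reached. The count was also 1 for the smooth muscle list, which was not called, against 6 for the cholesterol and 11 for the leukocyte list.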

How the results depend on the processing

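All alternatives except the joint leaving out of 2wk replicate 2 and 4wk replicate 2 were fixed before the data were examined. Of the 48 entries for genes named by smallest p, 47 kept their direction under all alternatives run. A kept direction is likely in advance, since these genes were picked by their p in the same data. The entries that passed the threshold under an alternative did so mostly without 2wk replicate 1, where 2wk replicate 2 stands alone for its age. The counts of probe sets stayed at 0 in all comparisons with pseudocount 1, no filter, the stricter filter, quantile normalization, unscaled values, no intensity trend and robust eBayes. In limma, a pseudocount of 64 gave 1 probe set at 8 against 2 weeks, fitting only the 4 samples compared gave 1 at 4 against 2 weeks, and a slope on age in weeks gave 1 (adjusted p = 0.0456), against 0 with log2 age. With the replicate number as a block, 8 probe sets passed at 8 against 2 weeks (ABCC8, SERPINI1, HPGD, PTI, NT5E and 3 unnamed) and 5 in the F test, and 4, 4 and 5 lists at 8 against 2, 4 against 2 and 8 against 4 weeks, with the meiosis call lost (camera adjusted p = 0.0816); the replicate numbers share nothing stated by the labels, and the replicate differences of 2 ages correlated across probe sets at 0.205, -0.00481 and -0.0597. Without the filter, with the stricter filter and with quantile normalization, 3 lists passed at 4 against 2 weeks in place of 5, and with either pseudocount 4. Without the filter 2 lists passed at 8 against 2 weeks in place of 3 and 3 at 8 against 4 weeks in place of 4, as many as with quantile normalization there. The variance models were not run for the lists, since camera moderates the variances by a setting of its own. With estimated correlations, where camera has the 3 residual degrees of freedom, 0, 0 and 0 lists passed in the 3 comparisons. The cause of these shifts was not tested.

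Leaving out 1 array at a time (which assumes that the lone sample varies like the other ages), or the pair named above, moved the number of probe sets between 0 and 1927 at 8 against 2 weeks, 0 and 1128 at 4 against 2 weeks, 0 and 4 at 8 against 4 weeks, 0 and 868 in the F test and 0 and 1 for the difference of steps. The highest values of the first, second and F test counts came without 2wk replicate 1, where 2wk replicate 2 stands alone for its age (1381 higher and 546 lower at 8 weeks). Without the pair the counts were 73, 13, 4 and 61. The number of lists ranged from 2 to 10, 0 to 5 and 1 to 5. Lists that turned direction were leukocytes at 8 against 2 weeks (-0.92 to 0.0306) and at 4 against 2 weeks (-0.76 to 0.21), oxidative phosphorylation at 4 against 2 weeks (-0.39 to 0.0639), and cholesterol biosynthesis at 4 against 2 weeks (-0.0488 to 0.53) and 8 against 4 weeks (-0.0564 to 0.52). Genes with small changes at 8 against 2 weeks turned too: AMH (-0.33 to 0.00788), FSHR (-0.37 to 0.0627), INHA (-0.15 to 0.23), INHBA (-0.0391 to 0.28), STAR (-0.0702 to 0.47), CYP11A1 (-0.0568 to 0.30), CYP17A1 (-0.18 to 0.65), INSL3 (-0.17 to 0.41), UCHL1 (-0.61 to 0.18), POU5F1 (-0.79 to 0.0637), HBB (-2.37 to 1.19) and RPL29 (-0.51 to 0.0753). Other probe sets gave -0.81 for AKR1C4 (8 against 4 weeks), -0.0729 for LSS and 0.10 for MAEL (-0.74 with a further one). Without turning direction, other probe sets moved the change by more than 1.5 times for NT5E at 8 against 4 weeks (0.0431), MADCAM1 at 8 against 4 weeks (-0.43), C5H12orf75 (0.55 at 8 and 0.70 at 4 against 2 weeks), NUDT4 (0.69 and 0.73), and at 8 against 2 weeks LHCGR (1.01), KIT (0.54 and 0.16), CDH5 (-0.34), STRA6 (-0.39) and CLDN11 (1.48). The cause was not tested. Probe sets below a signal of about 28.1, the highest of the Bacillus controls, carry no reliable direction.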

Other observations

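The gene groups and probe sets in this part were chosen after their values were seen. Interferon-stimulated genes were higher in 8wk replicate 1 than in 8wk replicate 2 for 18 of 18 measured genes. The mean of this list was 0.91 in 8wk replicate 1 and between -0.33 and 0.08 in the other arrays. ISG15, a ubiquitin-like protein induced by interferon, had a signal of 1109.9 there and 165.8 in the other replicate, MX1, an antiviral GTPase, 1404.0 and 393.6, RSAD2 274.5 and 64.8, and IFI44 213.9 and 56.4. In 2wk replicate 2, ISG15 was at 576.3 and RSAD2 at 64.6.

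For HPGD, the enzyme that inactivates prostaglandins, the dimmer of its probe sets had signals of 64.2 and 28.2 at 2 weeks and 254.4 and 204.5 at 8 weeks, and the brighter 204.5 and 83.1 against 457.4 and 387.1. The probe sets with the smallest p at 8 against 2 weeks included unnamed ones. The first had signals of 567.9 and 484.6 at 2 weeks, 297.7 and 425.6 at 4 weeks and 58.4 and 108.8 at 8 weeks (limma adjusted p = 0.0713). A second went the other way, at 125.8 and 65.3, 401.0 and 234.7, and 477.1 and 598.3, as did a further one, at 19.5 and 66.5, 275.5 and 473.5, and 736.0 and 263.8. A probe set named for the milk protein gene CSN2 ranged from 538.9 to 5115.8 over the arrays, while the brightest value of the other CSN2 probe sets was 21. BOLA-N, a class I histocompatibility gene, was at 3316.2 in 4wk replicate 2 and between 283.1 and 906.1 elsewhere, and another unnamed probe set at 1834.2 in 8wk replicate 2 and between 1.40 and 48.2 elsewhere.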
